A study of Mus musculus with 12 samples.

How the data were processed

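RNA from the livers of 12 male 129SV mice was measured on Affymetrix Mouse Genome 430 2.0 arrays, oligonucleotide arrays that hold several probe sets for many genes. The 6 wild-type and 6 Sirt4-knockout animals were littermates killed after a 16-h fast, and each animal had 1 array. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns and converted to biotinylated cRNA. Groups came from the genotype label. Replicate numbers follow the order of the records and pair no animals.

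The deposited values are intensities on a linear scale, made by the authors before deposit. RMA is named in the submitters' processing notes, with no version given. The intensities reach 0 in 689 cells from 514 of 45037 probe sets, so they are neither on a log scale nor bounded above background. Array medians lay between 36.6 and 38.69, so the arrays had been brought to a common level. The value table and the authors' deposited fold-change table hold the same intensities. The authors' deposited table adds means and standard errors of intensity, a signed fold change, a t statistic, which is a score, and 2 columns of unadjusted p-values. The second p-value column is blank for 7390 probe sets, all with a wild-type mean intensity of 10 or less. Its last line states that 288 genes passed the authors' filter, whose criteria are not given in the sources used here. The meaning of a mark on 23 probe sets is not given either. The tables hold no control probe sets, so RNA degradation could not be measured from them.

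In the authors' deposited table, the block of symbols, titles and gene numbers at the right does not belong to the rows it stands on. Its accession equalled the row's own accession on 1 row as placed, and on all 45037 rows once both sides were put in probe set order. Genes were therefore taken from each row's own gene number (36239 probe sets) or through its accession (844 probe sets), and named from a RefSeq table of the mouse assembly GRCm38. A further 6672 probe sets matched no gene, and 1282 matched several and were not named. The 37083 probe sets with 1 gene cover 17997 genes. The files name no genome build, so no coordinates are given.

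For each gene the probe set with the highest mean over the 12 arrays was used. Intensities were tested as log2(intensity + 50) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend), with Benjamini-Hochberg adjustment over 17997 genes and a threshold of 0.05, two-sided. A fold change on this scale understates the change of dim genes. The written design assumed log2 values and named no offset. The offset of 50 was preferred from a look at spread against level that ignored genotype, but gene tests with offsets of 16 and 50 had been run side by side before 50 was settled, and the 1 gene called depends on that choice. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.0639. Arrays were simulated for this comparison from the means and spreads of the same 17997 genes, with 200 genes changed by 0.3 to 1.5 on the log2 scale. The gene test recovered 48% of genes changed by 0.3, 94% of those changed by 0.5 and 100% of those changed by 1 or 1.5. It also called 14 unchanged genes. Many changed genes ease the Benjamini-Hochberg threshold, so these shares do not carry over to the real comparison, where 1 gene passed. There Lipg, with a log2 fold change of 0.50, had an adjusted p of 0.463. The simulated genes varied independently, which real ones do not.

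The design fixed 37 gene lists before the data were examined: fuel metabolism, nuclear receptor targets, stress responses, sex-biased and clock genes, and markers of the cell types a liver sample can hold. Of their 790 symbols, 761 were measured. Lists were tested with camera at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 37 lists. Camera with an estimated correlation, fry, and exact two-sided permutation of the animals on each list's mean served as checks. Of 100 simulated unchanged lists of 25 independent genes, 1% had an unadjusted camera p under 0.05. Because those genes were independent, this says nothing about lists whose genes vary together. List means per animal are means of log2 values centred per gene over the 12 arrays. Medians of lists were also set against 10000 random lists matched on mean intensity.

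The rule for named genes, also fixed beforehand, takes Sirt4, then 12 genes per direction: those past the threshold by size of change, with the remaining places going to the smallest unadjusted p. Unnamed clone-type symbols are passed over. It adds up to 4 members of each list by smallest p and 19 genes of fasting metabolism and the sirtuin family. Some genes the rule takes are not reported here. Genes named under the smallest-p part are given as values, not as changes.

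Title numbers fall into a 7200 series (2 wild type, 5 knockout) and a 7500 series (4 wild type, 1 knockout). The labels do not say what the number means. It was treated as a possible batch, as a fixed effect and by exact permutation of genotypes within the series (105 arrangements, smallest two-sided p 0.00952). Alternatives listed before the data were examined covered centring, quantile normalization, a filter on dim genes, other choices of probe set, the variance model, array weights, the title series, a title suffix carried by 3 knockout arrays, leaving out each array, the list test and the authors' p-values. Offsets of 16, a floor of 10 without offset, the permutation tests of gene lists, leaving out both wild type replicates 5 and 6 and a heat shock list were added after seeing the data. Exact permutation of the 12 animals for Sirt4 was fixed beforehand. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.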

Results

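Gene expression was compared in the livers of fasted mice with and without SIRT4, a sirtuin of the mitochondrial matrix. The study asked how fatty acid catabolism and the activity of PPARalpha, the nuclear receptor that drives fat oxidation in fasting, differ in SIRT4-knockout liver. The 12 arrays were 6 wild-type and 6 Sirt4-knockout male littermates, 1 array per animal. Correlations between arrays ran from 0.989 to 0.996. Wild type replicate 6 lay farthest from the rest on the first principal component (score -16.7, against -9.11 to 6.35 for the other arrays). P-values of the gene test and of permuted animals measure the spread between animals. Camera at the preset correlation takes genes as nearly independent, so its p-values understate that spread where a list's genes vary together. The Fisher test of genes near Sirt4 compares genes, not animals. The genotypes were spread unevenly over the 2 series of title numbers.

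Sirt4 itself was lower in the knockout. Its only probe set (Entrez gene 75387) read 172 ± 14.5 in wild type and 104 ± 16.4 in knockout (intensity, SD, n = 6), so the knockout kept 60.7% of the wild-type signal. The groups did not overlap: wild-type animals ranged from 153.3 to 186.99 and knockout animals from 81 to 120.68. The log2 fold change was -0.53 (SE 0.071, limma adjusted p = 0.0359), and the exact two-sided permutation p of 0.00216 was the smallest that 924 arrangements allow. Whether this probe set lies inside the deleted part of the gene is not given in the sources used here, so it is a limited check of the genotype labels. The call depends on the offset, chosen after the data were seen: the adjusted p was 0.141 with an offset of 16 and 0.235 with a floor of 10. It was also lost on leaving out any 1 of wild type replicates 1 to 5 or knockout replicates 1, 2, 3 and 5 (adjusted p 0.0528 to 0.162) or both wild type replicates 5 and 6 (0.223), and with the title series as a fixed effect (log2 fold change -0.50, adjusted p = 0.610).

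**Figure D1:**
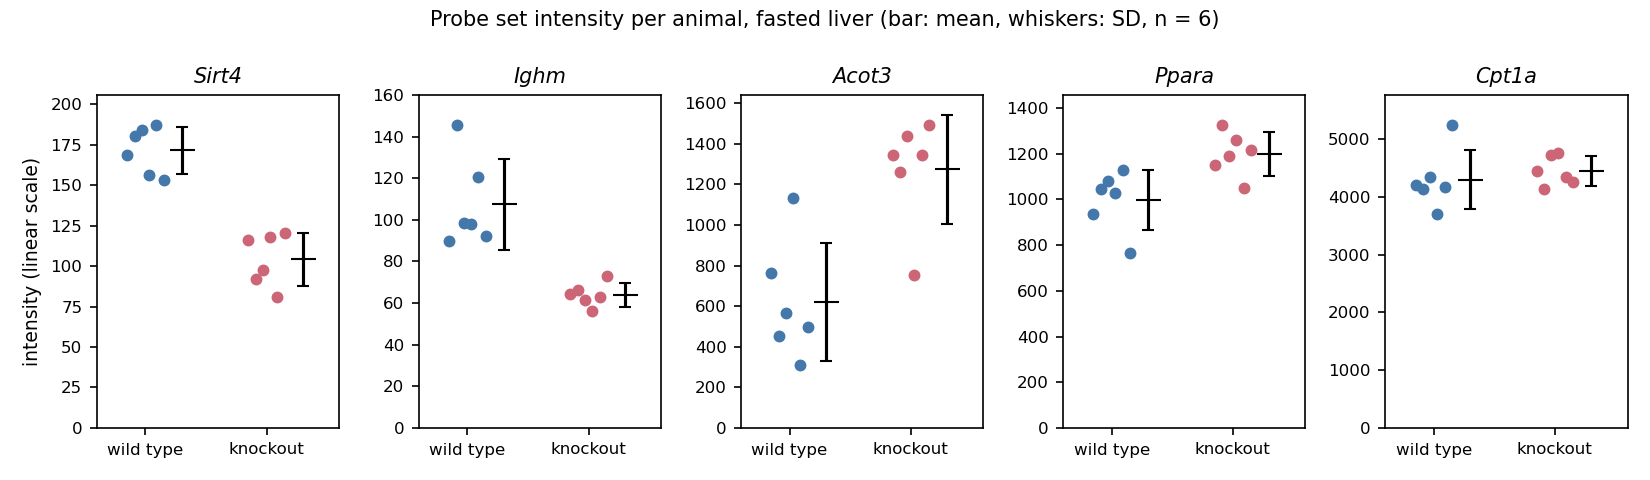
Intensity on the linear scale (y axis, from 0) of 5 genes in each wild-type and Sirt4-knockout animal; points are animals, the bar is the mean and the whiskers are the SD (n = 6). Sirt4 and Ighm do not overlap between genotypes, the Acot3 means are 620 and 1274, and Cpt1a reads 4297 and 4444.

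No other gene passed the threshold. With limma, 0 genes were higher and 1 was lower in the knockout, against 1132 genes at an unadjusted p under 0.05 (564 higher, 568 lower), or 6.29% of those tested. Centring each array on its median moved that split to 882 higher and 361 lower. In the authors' deposited table, 765 probe sets had a P under 0.05 (476 higher, 289 lower) and 2006 a p under 0.05 in the second p-value column, with 0 after adjustment in either. The groups did not overlap for 45 genes, 0.250% of the total, where chance gives 0.216%.

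The 12 genes nearest the threshold on the higher side did not pass and are given as values. Lipg, endothelial lipase, read 65.2 ± 16.7 in wild type and 112 ± 16.6 in knockout (log2 fold change 0.50). Fitm2, an endoplasmic reticulum protein needed for lipid droplet formation, read 634 ± 71.5 and 814 ± 41.5 (0.34). Acot3, a peroxisomal acyl-CoA thioesterase, had the largest log2 fold change of the 12 on the scale with the offset. It went from 620 ± 292 to 1274 ± 266 (1.06, SE 0.23, limma adjusted p = 0.589), and its second probe set gave 1.26. Without the offset Hspa1a changed more, with a fold change of 2.58 in the authors' deposited table against 2.05 for Acot3. One knockout animal, replicate 4, lay apart from the other 5 for Acot3, as did single knockout animals for Fitm2, Nxnl2 and Hadha. A1cf, the cofactor of apolipoprotein B mRNA editing, had a log2 fold change of 0.27, the retinol dehydrogenase Rdh16 0.28, and Irs1, a docking protein of the insulin receptor, 0.26. Hspa1a, an inducible HSP70 chaperone, read 71.3 ± 23.2 and 183 ± 75.0 (0.89). The remaining places went to the transporter-family gene Slc22a23 (0.23), Tdrp (0.26), the RNA-binding Khdrbs3 (0.35), the metalloproteinase Mmp23 (0.27) and Fam214a (0.31). Their adjusted p-values ran from 0.463 to 0.726.

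On the lower side, the gene after Sirt4 was Ighm, the heavy chain of IgM, at 107 ± 21.7 in wild type and 64.0 ± 5.68 in knockout (log2 fold change -0.46, limma adjusted p = 0.214). Its 6 probe sets disagreed, with log2 fold changes from -0.98 to 0.058. Cxcr4, a chemokine receptor of leukocytes, read 27.1 ± 4.46 and 14.0 ± 4.11 (-0.27), and Shc3, a signalling adaptor, 19.8 ± 4.74 and 7.76 ± 3.71 (-0.27). Rgs5, a G-protein regulator of pericytes, read 515 ± 38.8 and 434 ± 21.8 (-0.22). The others were Tdrkh (-0.36), Fbln1 (-0.33), which encodes the matrix protein fibulin 1, Shfl (-0.26), Mepce (-0.21), Zfp867 (-0.20), Nxnl2 (-0.20) and Samd4 (-0.17). Probe sets of Fbln1 and Mepce disagreed in sign. Cxcr4, Shc3, Zfp867, Nxnl2 and Mmp23 in both groups, and Fbln1, Tdrkh and Samd4 in the knockout, lay below the median intensity of the arrays, where signal is close to background. Adjusted p-values from Cxcr4 on were 0.528 to 0.747.

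Genes of fat oxidation were called higher in the knockout as a group at the preset correlation of the list test, and not at an estimated one. The 35 measured PPARalpha targets had a median log2 fold change of 0.079, and 27 were above 0 (camera adjusted p = 9.45e-06, and adjusted p = 0.265 with an estimated correlation). In the mitochondrial beta-oxidation list the median was 0.063 with 20 of 22 above 0 (5.60e-05, and adjusted p = 0.376 with an estimated correlation). In the peroxisomal and microsomal oxidation list it was 0.068 with 22 of 24 above 0 (5.32e-05, and adjusted p = 0.265 with an estimated correlation). Wild type replicates 5 and 6 had the lowest PPARalpha target means of all animals (-0.146 and -0.199, against a mean of -0.0029 for the other 4 wild types) and the highest means of acute phase genes (0.940 and 0.733) and neutrophil markers (0.293 and 0.427). Without these 2 animals, a choice made after seeing the data, the difference in list means went from 0.119 to 0.062 for PPARalpha targets, from 0.075 to 0.044 for beta-oxidation and from 0.119 to 0.082 for the peroxisomal list. Camera adjusted p-values were then 0.0128, 0.0350 and 0.0132, and with an estimated correlation the adjusted p-values were 0.599, 0.713 and 0.621. Exact permutation of the remaining animals (210 arrangements) gave unadjusted p = 0.0143, 0.0952 and 0.0476.

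Among PPARalpha targets, Aldh3a2, which oxidises fatty aldehydes, read 2129 ± 493 in wild type and 2911 ± 222 in knockout (0.47), G0s2, an inhibitor of adipose triglyceride lipase, 2760 ± 1096 and 3961 ± 524 (0.60), and Pex11a, which acts in peroxisome division, 2010 ± 637 and 2672 ± 136 (0.46). In the beta-oxidation list, Acot2 had a log2 fold change of 0.39 and Acsl1, which activates long-chain fatty acids, 0.14. No member passed the gene test over all genes. Adjusted over the list alone, 0 of 35 PPARalpha targets, 0 of 22 beta-oxidation genes and 1 of 24 peroxisomal genes passed, the 1 being Acot3. Exact permutation of the 12 animals gave, in the same order, unadjusted p = 0.00649, 0.0260 and 0.0130 (adjusted p 0.0801, 0.192 and 0.120), and within the title series 0.0190, 0.124 and 0.0190. Branched-chain amino acid catabolism and B cell markers had the same unadjusted exact p-values as PPARalpha targets (0.00649, and 0.0190 within the series). Of the 35 PPARalpha targets, several also belong to an oxidation list, so the lists are not independent.

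The central enzymes of the fasting response differed little. Cpt1a, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, read 4297 ± 510 in wild type and 4444 ± 254 in knockout (log2 fold change 0.054), and its other probe sets had the opposite sign (-0.072 and -0.19). The acyl-CoA dehydrogenases gave 0.089 (Acadm), 0.073 (Acadl) and 0.033 (Acadvl), and the trifunctional protein subunit Hadha -0.0098. Pdk4, a kinase that blocks pyruvate oxidation, gave 0.073, Angptl4 0.099, Acot1 0.26 and Cyp4a14 0.074. The hormone Fgf21 had a log2 fold change of -0.18 and the fatty acid transporter Cd36 -0.32. Ppara read 998 ± 130 and 1199 ± 94.5 (0.26, SE 0.082, limma adjusted p = 0.747), and its coactivator Ppargc1a gave -0.097. The sirtuins Sirt1, Sirt3 and Sirt5 gave 0.0028, 0.042 and 0.0045, malonyl-CoA decarboxylase (Mlycd) -0.020 and glutamate dehydrogenase (Glud1), an enzyme that SIRT4 is known to modify, -0.014. None of these genes passed the threshold, with adjusted p-values from 0.747 to 0.997. The signs for Cpt1a, Hadha, Pdk4, Sirt1, Sirt5, Mlycd and Glud1 changed under at least 1 other setting.

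**Figure D2:**
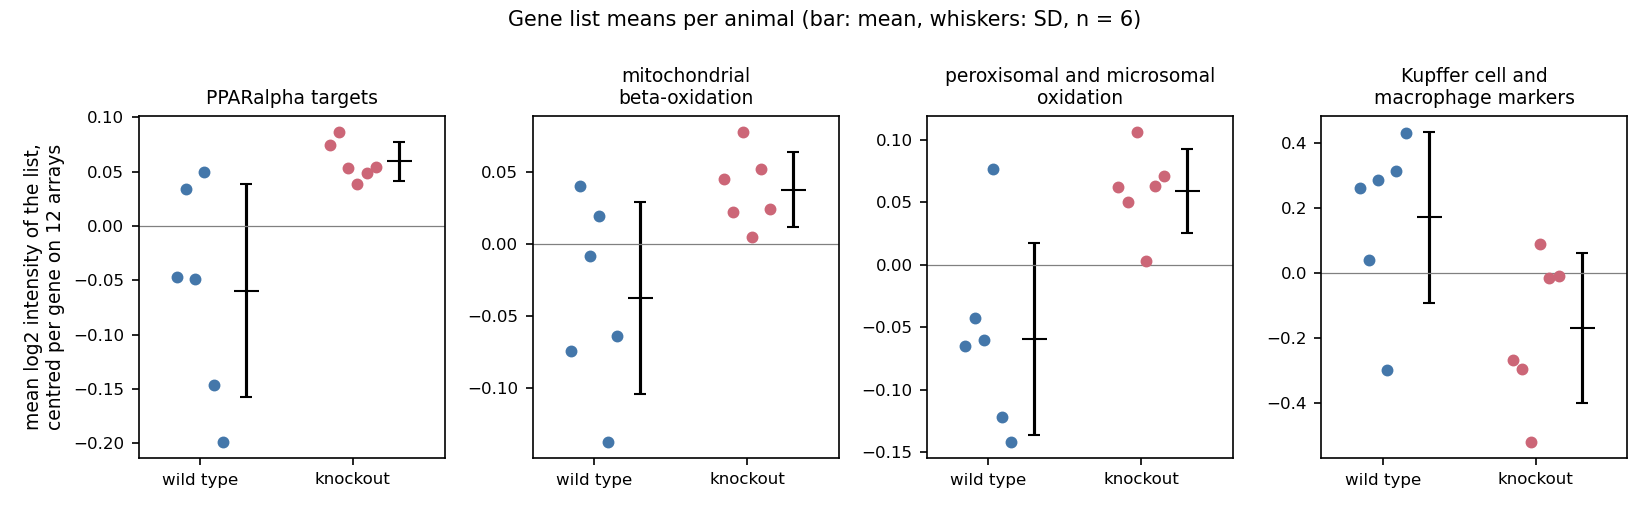
Mean log2 intensity of 4 gene lists per animal (y axis, centred per gene over the 12 arrays); points are animals, the bar is the mean and the whiskers are the SD (n = 6). The 3 fat oxidation lists lie higher on average in the knockout, and the macrophage list lower, with wild type replicate 4 at -0.30 among the knockout values.

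All 16 measured Kupffer cell and macrophage markers, genes of the resident phagocytes of the liver, were below 0, with a median log2 fold change of -0.32. The list gave camera adjusted p = 3.59e-12, and adjusted p = 0.289 with an estimated correlation. Lyz2, lysozyme, read 545 ± 177 in wild type and 337 ± 63.9 in knockout (-0.58), the scavenger receptor Marco 204 ± 95.7 and 96.8 ± 17.0 (-0.69), and the complement gene C1qb 492 ± 108 and 362 ± 95.6 (-0.40). Adjusted over the list alone, 11 of 16 macrophage markers passed, all narrowly (limma adjusted p 0.0479 to 0.0499), as against 0 over all genes. The markers vary together (estimated correlation 0.69), so these 11 are not independent of each other. The list mean differed by -0.342 (SE 0.143) over all animals, with an exact two-sided permutation p of 0.0476, and by -0.295 (SE 0.172) within the title series (0.133). Without wild type replicates 5 and 6, which had the 2 highest macrophage means (0.313 and 0.429), the median was -0.22 and the exact p 0.157.

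Among 11 B cell markers the median was -0.060 (camera adjusted p = 7.31e-04, and adjusted p = 0.174 with an estimated correlation), led by Ighm and the immunoglobulin joining chain Jchain (-0.67), for which wild type replicate 6 stood above the others. Stellate cell and fibroblast markers had a median of -0.071 with 12 of 17 below 0 (0.00553, and adjusted p = 0.376 with an estimated correlation), among them Rgs5 and the collagen gene Col1a2 (-0.20). Adjusted over the list alone, 2 B cell markers (Ighm, Jchain) and 1 stellate marker (Rgs5) passed. Acute phase genes had a median of -0.061 and neutrophil markers -0.084 (camera adjusted p = 0.00553 and 0.0392, and adjusted p = 0.701 and 0.422 with an estimated correlation). Without wild type replicates 5 and 6 the acute phase median turned to 0.090 (camera adjusted p = 0.0669) and the neutrophil median was -0.013 (0.565). With the title series as a fixed effect both calls were lost as well (medians -0.013 and -0.096, camera adjusted p = 0.289 and 0.110). Single arrays ended them too: wild type replicate 5 or 6 or knockout replicate 1 or 5 for acute phase genes (up to 0.514), and wild type replicates 4, 5 and 6 or knockout replicates 1, 2, 4 and 6 for neutrophil markers (up to 0.166). Erythroid markers had a median of 0.085 (camera adjusted p = 0.0112, and adjusted p = 0.376 with an estimated correlation), and the call was lost with the title series as a fixed effect (0.0934) and without knockout replicate 5 (0.161). Sinusoidal endothelial markers had a median of 0.047, T and NK cell markers -0.0079 and hepatocyte markers -0.0058, and none of these lists passed.

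Genes of the TCA cycle and pyruvate dehydrogenase had a median log2 fold change of 0.055 with 22 of 26 above 0 (camera adjusted p = 0.00117, and adjusted p = 0.376 with an estimated correlation), among them Idh2 (923 ± 105 in wild type, 1086 ± 81.2 in knockout) and Idh3a (803 ± 35.2 and 915 ± 102), isocitrate dehydrogenase genes. Branched-chain amino acid catabolism had a median of 0.067 with 17 of 22 above 0, led by Mccc2 (0.12; camera adjusted p = 0.00159, and adjusted p = 0.174 with an estimated correlation); the call was lost after quantile normalization (0.0522) and in the 7200 series only (0.126). Oxidative phosphorylation gave 0.029 with 42 of 56 above 0, led by Ndufa9 (0.091; camera adjusted p = 0.00553, and adjusted p = 0.580 with an estimated correlation). Cholesterol synthesis had a median of 0.094, with 0.22 for Fdft1, which encodes squalene synthase (camera adjusted p = 0.00323, and adjusted p = 0.588 with an estimated correlation). One knockout animal set the cholesterol call, which had adjusted p = 0.683 without knockout replicate 3. The TCA and oxidative phosphorylation calls were lost without wild type replicates 5 and 6 (camera adjusted p = 0.154 and 0.497), the latter also without replicate 5 alone (0.232), with the title series as a fixed effect (0.0953), in the 7200 series only (0.427), after quantile normalization (0.621) and among the brighter genes.

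Circadian clock genes had a median of 0.10, with 0.33 for Hlf and 0.41 for Wee1 (camera adjusted p = 0.0175, and adjusted p = 0.422 with an estimated correlation), and Hlf passed when adjusted over the list alone. Medians were 0.073 for bile acid synthesis and transport, 0.070 for fatty acid synthesis and 0.042 for CAR and PXR targets. Their camera adjusted p-values were 0.0260, 0.0392 and 0.0498, and with an estimated correlation the adjusted p-values were 0.423, 0.376 and 0.568. Abcc3, an exporter of bile acid conjugates that belongs to the CAR and PXR targets and to bile acid transport, read 3121 ± 377 and 3692 ± 198. The clock call was lost without wild type replicate 1 or 6 or knockout replicate 2 (up to 0.166). The bile acid call was lost without wild type replicate 1 or 6 or knockout replicate 1, 3 or 5 (up to 0.181). The fatty acid synthesis call was lost without wild type replicate 1, 2, 4 or 5 or knockout replicate 3, 5 or 6 (up to 0.190), and the CAR and PXR call without wild type replicate 1 or 6 or knockout replicate 2, 3 or 6 (up to 0.465). In the 7200 series only, the cholesterol, bile acid, erythroid and neutrophil calls were lost (camera adjusted p = 0.318, 0.126, 0.318 and 0.536), and after quantile normalization the bile acid, fatty acid synthesis, CAR and PXR and neutrophil calls (0.167, 0.167, 0.0924 and 0.0847). In all, camera called 17 of 37 lists (12 higher, 5 lower), and 0 held with an estimated correlation, with fry or with adjusted exact permutation of the 12 animals. Without wild type replicates 5 and 6 it called 11: the clock, bile acid, CAR and PXR and erythroid calls were among those lost, and endoplasmic reticulum chaperones (median 0.14) and male-biased genes (-0.089) were added (adjusted p = 0.00218 and 0.0350, and adjusted p = 0.713 for both with an estimated correlation).

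**Figure D3:**
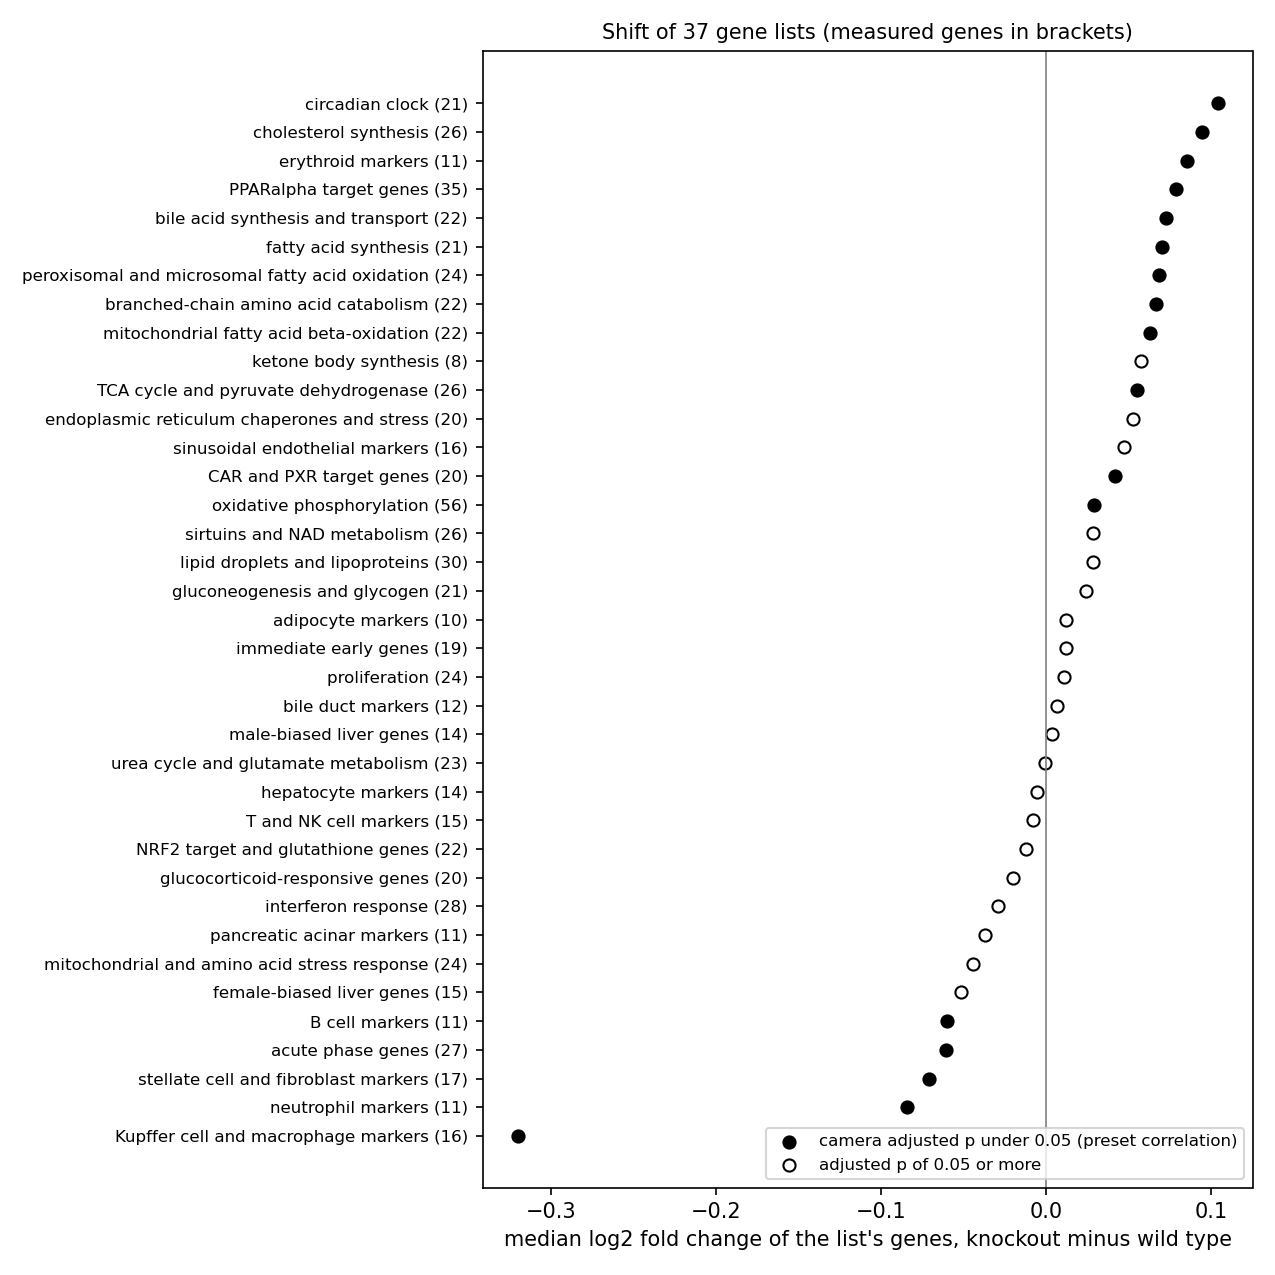
Median log2 fold change, knockout minus wild type (x axis), of the measured genes of each of 37 lists (y axis, number of genes in brackets). Filled points passed camera at the preset correlation; 17 are filled, and the macrophage list stands apart at -0.32.

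The remaining lists did not pass. Median log2 fold changes were 0.057 for ketone body synthesis, 0.052 for endoplasmic reticulum chaperones, 0.028 for lipid droplets and lipoproteins, 0.028 for sirtuins and NAD metabolism and 0.024 for gluconeogenesis and glycogen. They were -0.00083 for the urea cycle and glutamate metabolism, -0.044 for the mitochondrial and amino acid stress response, -0.012 for NRF2 targets, -0.029 for the interferon response and -0.020 for glucocorticoid-responsive genes. Immediate early genes gave 0.012, proliferation genes 0.011, male-biased liver genes 0.0035 and female-biased liver genes -0.051. Markers of bile duct, adipocytes and pancreatic acini gave 0.0063, 0.012 and -0.037. Camera adjusted p-values of these and the 3 cell type lists above ran from 0.0654 to 0.984. The median differed in sign from the mean or the test for glucocorticoid, proliferation, immediate early, adipocyte and bile duct genes.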

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

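Groups of 6 animals were searched for 1 animal far from the other 5, in 288 groups of values of named genes, list examples, list means and array totals. The search set aside 22, or 7.64%, where chance gives about 1 in 20. For each, the gap to the nearest animal is given as a share of the group's range. Knockout replicate 4 accounts for 6 of them, replicates 1 and 3 for 4 each, and no biological or technical explanation was tested.

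Knockout replicate 3 was highest for the cholesterol synthesis list (mean 0.649, next 0.0898, share 0.715), Hsd17b7 (0.725) and Hmgcs1 (0.710), and lowest for Saa3 (0.688). Knockout replicate 4 was highest for the acute phase list (mean 0.670, next -0.0993, share 0.713), Apcs (0.737), Orm1 (0.633) and S100a9 (0.851), and lowest for Acot3 (0.751) and Acot4 (0.655). Knockout replicate 1 was lowest for gluconeogenesis and glycogen (0.688) and Gpam (0.718), and highest for bile duct markers (0.646) and Fitm2 (0.731). Knockout replicate 6 was highest for Nxnl2 (0.694) and lowest for Hadha (0.665).

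Wild type replicate 6 was highest for Jchain (0.706) and for the urea cycle and glutamate list (0.660). Wild type replicate 5 was lowest for endothelial markers (0.655) and Ndufb5 (0.705). Wild type replicate 1 was highest for Bank1 (0.695) and wild type replicate 3 for Gpam (0.631).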

How the results depend on the processing

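The offsets, the floor, the list permutations and leaving out both wild type replicates 5 and 6 were chosen after seeing the data, and the cause of a lost call was not tested. Genes higher stayed at 0 in every setting run. Genes lower were 0 with all probe sets, the title series as a fixed effect, the 7200 series only, offset 16, floor 10, both wild types left out, and the authors' P values adjusted; leaving out 1 array gave 0 to 1. The Sirt4 log2 fold change stayed negative: -0.53 (adjusted p = 0.0534) with all probe sets, -0.50 (0.610) with the series, -0.58 (0.921) in the 7200 series, -0.65 (0.141) with offset 16, -0.73 (0.235) with floor 10, -0.53 (0.223) with both wild types left out, and -0.558 to -0.482 without 1 array (0.0364 to 0.162). Fewer animals or residual degrees of freedom were left in the series settings.

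Lists with a shift, 17 in the main test, were 11 after quantile normalization 10 among the brighter genes only (8999 tested), 11 with both wild types left out, and 12 to 19 without 1 array, with 12 lacking wild type replicate 6. They were 0 with an estimated correlation, fry, exact permutation of the 12 animals and exact permutation within the series; for the last 2 a call needs at least 2 and 8 lists at the smallest possible p, so the series count of 0 was nearly fixed by the design. For beta-oxidation these gave a median of 0.063 (0.376, then 0.221) and means of 0.075 (0.192) and 0.063 (0.493); for PPARalpha targets 0.079 (0.265, then 0.117) and means of 0.12 (0.0801) and 0.093 (0.117). Under camera at the preset correlation, beta-oxidation, peroxisomal, PPARalpha, macrophage, stellate and B cell lists were called in all 25 settings. The acute phase list reversed to 0.044 in the 7200 series only (0.536) and to 0.090 with both wild types left out (0.0669), where male-biased genes reversed to -0.089 (0.0350). Median centring shifted the median of all genes to 0.018 and the unadjusted split to 882 higher and 361 lower; the brighter genes gave 436 and 215. For the 42 other named genes, 1042 values under alternatives stayed on the same side of the threshold, and 37 changed sign, in 7 genes. The covariate from control probe sets was not run, as the tables hold none. Signal near background limits dim genes such as Shc3 and Cxcr4.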

Other observations

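The heat shock list, the fat oxidation genes taken as 1 set, the comparison of spread and the tests of cell share, tissue stress and title series for fat oxidation and heat shock were chosen only after results were seen. The splits, the series test of macrophage markers, the matched lists and the neighbours of Sirt4 were written down after the list results were seen but before their own values were. Leaving out each array was listed before the data were examined.

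Of 24 heat shock genes, a list formed after 7 of its members, Hspa1a among them, had been looked at, 22 had a positive log2 fold change (median 0.20), with an exact p of 0.0519 for the list mean over all animals. Values are given for Hspa1b (3600 ± 1608 in wild type, 6074 ± 1730 in knockout), the stress-response zinc finger gene Zfand2a (227 ± 33.8 and 320 ± 56.0), the HSP40 gene Dnajb1 (810 ± 155 and 1128 ± 287) and the co-chaperone Bag3 (446 ± 105 and 626 ± 133). None passed over all genes, and adjusted over the list alone, which is not independent evidence here, Hspa1a and Zfand2a passed. Some immediate early genes went opposite ways: Egr1, a growth factor-induced transcription factor, read 349 ± 91.2 and 201 ± 72.2, and Jun 228 ± 32.9 and 323 ± 64.8, both with adjusted p = 0.0284 over their list alone and 0.747 over all genes. Asns, asparagine synthetase, read 943 ± 568 and 395 ± 130 (log2 fold change -1.05, limma adjusted p = 0.747).

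The variance between animals was larger in wild type for 56.9% of genes, with a median ratio of 1.20 (exact two-sided permutation p = 0.0303 over 462 splits of deviations from the group means). The wild types are divided more evenly over the title series than the knockouts, and with the series taken out the ratio was 1.19 and the p 0.0628, so a difference in spread is not established. The median log2 ratio of 0.27 was 0.14 without wild type replicate 6.

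Splits of the 12 arrays into 6 and 6 were drawn to 100 in all, the real one included, and each count of splits below includes it. As many genes in 1 direction, higher or lower, as the real 1 lower gene came from 5 splits (highest other 1), and as many genes at an unadjusted p under 0.05 as the real 1132 from 16 (highest other 1319). Chance cannot be excluded for these 2 counts. The count of higher genes decides nothing, since the real value is 0 and all 100 splits must give as many (highest other 1). For the 17 shifted lists, 3 splits gave as many (highest other 18), and for the camera p of PPARalpha targets 2 did (5.11e-07, lowest other 9.08e-08). Both camera results fell under the limit of 5 in 100 set before the splits were run. That limit makes no allowance for the number of results tried this way, and the splits ignore the title series. Adjusted over all lists, the exact p of PPARalpha targets was 0.0801 over the 12 animals, so chance is not excluded here either. Within the title series the unadjusted exact p was 0.0190, and the adjusted one of 0.117 could hardly pass by design. For beta-oxidation 6 splits gave a camera p as small (6.05e-06, lowest other 1.14e-08), which is over the limit, and chance is not excluded. No limit was set for the macrophage list. An arbitrary split gave it a smaller camera p than the real one (minus log10 of the p 17.0, against 13.0). The smallness of that camera p alone therefore does not set the real grouping apart.

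The macrophage shift was not set by 1 array, since the median nearest 0 on leaving out any array was -0.26. A smaller share of all cells other than hepatocytes would lower endothelial markers too. Their mean differed by 0.029, by -0.010 within the title series, and by -0.028 without wild type replicates 5 and 6. Means of other such lists went both ways: stellate -0.079, B cell -0.14, neutrophil -0.16, bile duct -0.026, T and NK cell -0.0095 and erythroid 0.12. The endothelial minus macrophage mean differed by 0.371 (SE 0.158, exact p = 0.0368) over all animals. Within the series it differed by 0.285 (SE 0.184, exact p = 0.152), a similar size with a wider error, so it does not decide. The title series stays open as well, since the macrophage difference of -0.295 within it is close to the whole one but its exact p is 0.133. Part of the difference rests on wild type replicates 5 and 6, which also had the highest acute phase and neutrophil means. Without these 2 animals the difference in macrophage means went from -0.342 to -0.242 (exact p = 0.157). Fewer or less active macrophages in knockout liver may account for the shift. That is a hypothesis that these data do not separate from the series or from the state of these 2 animals.

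For fat oxidation, the 68 genes of the 3 lists together differed by 0.10 in their mean (exact p = 0.00433). Within the title series the difference was 0.089, a similar size (exact p = 0.00952, the smallest it allows). The set was formed after its lists were seen to shift, so this p is not independent support. Alone, the PPARalpha, beta-oxidation and peroxisomal lists had adjusted exact p-values of 0.117, 0.493 and 0.117 within the series, which is therefore not excluded. The median of the 68 genes, 0.063, lay above all 10000 lists matched on intensity (percentile 100), whose own median was 0.013. Transcripts of like abundance thus differed by less than the 68 genes. The genes of the matched lists were drawn singly and do not vary together as the 68 may, so the percentile does not measure the spread between animals. Cholesterol synthesis, whose call 1 knockout animal set, also reached percentile 100. Set against other hepatocyte genes, whose mean differed by -0.014, the difference was 0.116 (SE 0.057, exact p = 0.0433), and 0.098 within the series (SE 0.068, exact p = 0.171). The size changed little and the error grew with the uneven division of genotypes, so a larger share of hepatocytes is left neither excluded nor favoured. Part of the difference rests on wild type replicates 5 and 6, which had the highest acute phase means. Without these 2 animals the difference in PPARalpha target means went from 0.119 to 0.062. A higher PPARalpha activity in the knockout remains a hypothesis, which the PPARalpha targets Fgf21 and Cd36, with negative values, do not share.

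For the heat shock genes, the mean differed by 0.24 over all animals (exact p = 0.0519) and by 0.29 within the title series (exact p = 0.0381). The difference from immediate early genes, which general tissue stress at collection would raise too, had an exact p of 0.0325. For the 17 members not looked at before the list was formed, the difference was 0.15 (exact p = 0.0779) and 0.19 within the series (0.0571), and against immediate early genes 0.13 (0.0758) and 0.17 (0.0476). The difference was larger within the series, yet these values pass too unevenly to exclude the series or tissue stress. How quickly each liver was taken is not given in the sources used here and may still matter.

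A knockout allele can carry neighbouring genes of the strain it was made in. Among the 100 measured genes nearest Sirt4, 5 had an unadjusted p under 0.05, against 6.29% of other genes (one-sided Fisher exact p = 0.761), too few to decide.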
